A study of Mus musculus with 6 samples.

How the data were processed

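RNA from the apex of the left ventricle of 6 female mice was measured on Affymetrix mouse expression arrays, with 1 array per mouse. Per the labels, the mice were littermates of 8 weeks on a mixed background of the C57B6 and B6129 strains, and both groups received tamoxifen at 20 mg/kg. The labels give the time of collection as 5 days after tamoxifen in one place and describe treatment for 5 days in another, so the number of injections is open. The 3 knockout mice carried a floxed and a null allele of Paxip1, the gene of the protein PTIP, together with a transgene in which the alpha myosin heavy chain promoter drives a fusion of Cre recombinase and a modified estrogen receptor. Tamoxifen lets this fusion protein enter the nucleus and delete the floxed allele in cardiomyocytes. The 3 control mice carried a floxed and a wild-type allele, and the labels name no Cre transgene for them.

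The deposited values are log2 expression values made by the authors with RMA (robust multi-array average, which corrects background, normalises between arrays and summarises the probes of a probe set), per the submitters' processing notes. The RMA software version is not given in the sources used here, and the log base was inferred from the range of the values, from 1.36 to 14.1. Labelled target was made with the NuGen Ovation biotin system, which amplifies the RNA, per the labels. Normalisation between arrays makes the arrays alike in their overall distribution, so a change in total RNA per cell cannot be seen in such values, and RMA compresses changes of dim probe sets. The medians of the 6 arrays lay between 5.15 and 5.26. For arrays, the number of mice limits the precision, and the median standard error of a log2 difference was 0.147.

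Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. Gene names came from the platform annotation, and symbols were updated through the Entrez identifier with a RefSeq gene table of the assembly GRCm38.p6. The annotation gave 1 gene for 34945 tested probe sets, several genes for 932, and did not list 9160, which stay unnamed here. The Entrez identifier of 34741 of the 34945 was found in the gene table. Each of the 18194 genes was represented by the probe set with the highest mean over all 6 arrays, and the other probe sets of a named gene were examined beside it. No coordinates are printed because the array annotation names no genome build.

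Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a variance trend or robust prior), as knockout minus control, two-sided, with group as the only term. P values were adjusted with the Benjamini-Hochberg method over all tested probe sets, and an adjusted p under 0.05 counted as passing. The moderated test had a median of 7.39 degrees of freedom. A single probe set was also tested by an exact permutation test of its 6 values, whose two-sided p cannot go below 0.1 for 3 against 3 mice.

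The genes to name were fixed before the data were examined: every probe set of Paxip1; the 12 largest increases and 12 largest decreases among genes that passed, whose groups did not overlap and whose mean in the higher group lay above the median of all probe set means; up to 4 members with the smallest p of each list described; and 9 genes of cardiac function and stress whatever their values, of which 1 is not analysed here. Predicted genes, genes without a symbol and Y-linked genes were not used for the largest changes. The named increases were chosen from 16 genes and the decreases from 30. Genes named outside the rule are said to be so.

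The 35 gene lists, 23 of pathways and 12 of cell type markers, were also fixed beforehand. Of their 793 entries, 719 were measured. A list of 5 or more measured genes was tested with limma's camera, which asks whether its genes shifted against all other genes, with a preset correlation between genes of 0.01. Camera with a correlation estimated per list, camera on ranks, and fry stood beside it. Fry's one-direction p asks whether the genes of a list move one way on balance and its mixed p whether they change in either direction, and neither compares the list with other genes. P values were adjusted over the pathway lists and separately over the cell type lists. Members were counted when adjusted over all probe sets and when adjusted over the list alone.

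The alternatives were a variance trend, a robust prior, array weights, 2 filters on dim probe sets, renewed quantile normalization, centring each array on its median, the replicate number as a block, leaving out each mouse in turn, the 4 arrays that share the leading digits of their description number (knockout 3 and all controls), other thresholds, a test without moderation, and the mean of all probe sets of a gene. Counting a gene when any of its probe sets passed was added after seeing the data. Results for Paxip1 were summarised as the number of its 4 probe sets that passed, a summary also chosen after seeing the data.

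The fits were tested on simulated data with 200 changed probe sets among 45037 and the spread of these arrays, in 20 runs. The changed probe sets were drawn from those above the median level, so recovery of dim ones was not tested. They recovered 51.9% of changes of 2-fold and 88.8% of changes of 4-fold, with 3.83% false calls. A shift of 0.3 of a list of 25 random probe sets gave an unadjusted camera p under 0.05 in 20 of 20 runs, and no unshifted list did. That rule is looser than the adjusted p by which lists pass here. The simulated genes were independent of one another. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.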

Results

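Gene expression was measured in the left ventricular apex of 3 adult mice with an induced deletion of Paxip1 and 3 littermate controls that kept a wild-type allele. PTIP, the protein of Paxip1, is a component of the nuclear complexes around the histone methyltransferases Kmt2c and Kmt2d. The labels name the mice as separate animals, numbered 1 to 3 in each group. The arrays resembled one another, with correlations between 0.989 and 0.995 over all probe sets and no identical columns. The first and second principal components held 28.9% and 28.2% of the variance, and control 1 stood apart on the first. The log2 difference between the 3' and 5' actin control probe sets, which grows as RNA degrades, was 1.51, 1.45 and 1.64 in the knockout mice and 1.85, 1.17 and 1.38 in the controls, highest in control 1. All mice are labelled female, and the brightest Xist probe set lay between 10.7 and 11.1 in all 6 while 9 Y-linked probe sets had a median of 2.24, near the lower end of the scale. The highest single value of these Y-linked probe sets was 5.42.

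The series asks which genes of the adult heart change after loss of PTIP, and Paxip1 itself checks the labels. Paxip1 fell in the knockout ventricles. The probe set 1423303_at read 6.05 ± 0.25 (SD, n = 3) in the knockout mice and 7.87 ± 0.20 (SD, n = 3) in the controls, a log2 difference of -1.83 (SE 0.17, limma adjusted p = 0.0240). Paxip1 probe sets 1423302_a_at and 1454943_a_at also fell, with differences of -1.58 (limma adjusted p = 0.0377) and -1.54 (limma adjusted p = 0.0299). The fourth Paxip1 probe set, 1434363_x_at, had a difference of -0.95 (limma adjusted p = 0.106) and did not pass. It had the highest mean over all 6 arrays (6.98) and so represents the gene. Paxip1 is therefore not among the 52 genes counted as passing below. All 3 knockout mice were below all 3 controls on each of the 4 probe sets, with an exact permutation p = 0.1, the smallest that 3 against 3 mice allow. The labels do not say which part of Paxip1 was deleted, so a probe set outside it would check nothing. The apex also holds cells other than cardiomyocytes, which keep the floxed allele, and the controls have 1 wild-type allele. The knockout mice carry a null allele instead of the wild-type one, which may lower Paxip1 without any induced deletion. No Paxip1 probe set passed when any single mouse was left out, although each difference kept its sign.

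**Figure D1:**
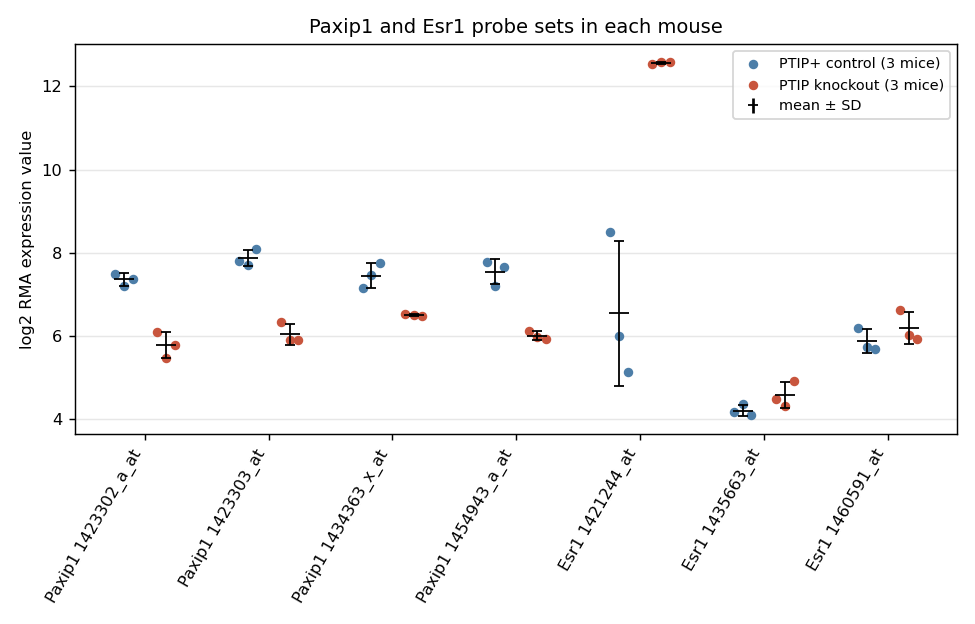
RMA expression values (log2, y axis) of the 4 Paxip1 and 3 Esr1 probe sets (x axis) in each mouse, with PTIP+ controls in blue, PTIP knockouts in red, and bars for mean ± SD of 3 mice. Knockouts lie below controls on every Paxip1 probe set, and on Esr1 probe set 1421244_at the knockouts read 12.57 ± 0.02 while the controls spread around 6.54 ± 1.74.

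The largest increase was in Esr1, the estrogen receptor alpha gene, whose probe set 1421244_at was 64.9-fold higher in the knockout ventricles. It read 12.57 ± 0.02 (SD, n = 3) in the knockout mice and 6.54 ± 1.74 (SD, n = 3) in the controls, a log2 difference of 6.02 (SE 0.75, limma adjusted p = 0.0476). The other Esr1 probe sets, 1435663_at and 1460591_at, differed by 0.37 and 0.32 and did not pass. The labels name a transgene with a modified estrogen receptor for the knockout mice alone. Among the controls the same Esr1 probe set read 8.49 in control 1, 6.0 in control 2 and 5.14 in control 3, and without control 1 the difference was 6.99 (limma adjusted p = 0.00240). Leaving out any other mouse ended the call, with limma adjusted p between 0.101 and 0.204.

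Apart from Esr1, the largest increases under the naming rule, which leaves out predicted and dim genes, were in Phactr3, Slc17a7, Lrrc52, Ttr and Ldhd. Phactr3, of a family that binds protein phosphatase and actin, rose by 2.44 on the log2 scale, from 5.31 ± 0.20 to 7.76 ± 0.07 (SD, n = 3 each, SE of the difference 0.13, limma adjusted p = 0.00746). Slc17a7, a vesicular glutamate transporter, rose by 2.13 from 6.93 to 9.06 with the same adjusted p. Lrrc52, an auxiliary subunit of Slo potassium channels, rose by 2.03, and Ttr, the carrier of thyroid hormone and of retinol-binding protein, by 1.95. Ldhd, the mitochondrial dehydrogenase of D-lactate, rose by 1.66 from 8.87 ± 0.34 to 10.54 ± 0.08 (SD, n = 3 each). T2 rose by 1.44 and Hspa1l, a chaperone of the Hsp70 family, by 1.42. Among muscle genes, Abra, an actin-binding activator of serum response factor signalling, rose by 1.39, and Klhl40, which stabilises thin filament proteins, by 1.36. Dct, an enzyme of melanin synthesis, rose by 1.28 and Clba1 by 1.22. The limma adjusted p of the genes from Lrrc52 to Clba1 lay between 0.0206 and 0.0496. The second probe set of Ldhd rose as well, by 1.65 (limma adjusted p = 0.0240), while the second probe set of Lrrc52, 1432914_at, was dim at 2.70 against 2.54 and differed by 0.16.

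Under the same rule, the largest decreases were in Eprn, Acot1, Alox5, Masp1 and Ddah1. Eprn, a long non-coding RNA, fell by 2.37 on the log2 scale, from 8.03 ± 0.24 to 5.66 ± 0.28 (SD, n = 3 each, SE of the difference 0.18, limma adjusted p = 0.0172), and was 5.18-fold lower. Acot1, a cytosolic acyl-CoA thioesterase, fell by 2.23 from 7.80 ± 0.28 to 5.56 ± 0.57 (SD, n = 3 each), and Alox5, the lipoxygenase at the start of leukotriene synthesis, fell by 2.03. Masp1, a serine protease of the lectin pathway of complement, fell by 1.99 (SE 0.12, limma adjusted p = 0.00746). Ddah1, which breaks down an inhibitor of nitric oxide synthases, fell by 1.86, and Frem2, a protein of basement membranes, fell by 1.73. Mrln, whose micropeptide inhibits the calcium pump of the sarcoplasmic reticulum in skeletal muscle, fell by 1.73 from 8.38 ± 0.10 to 6.65 ± 0.23 (SD, n = 3 each). Ntsr2, a neurotensin receptor, fell by 1.72, Flvcr2, a membrane transporter, fell by 1.53, and Polr1e, a subunit of RNA polymerase I, fell by 1.46. Kcnd3, a pore-forming subunit of the fast transient outward potassium current, fell by 1.45, and Slc38a4, an amino acid transporter, fell by 1.44. The limma adjusted p of these decreases other than Masp1 lay between 0.0148 and 0.0496. A second Slc38a4 probe set fell by 2.11 (limma adjusted p = 0.0184), and 2 further Ddah1 probe sets passed as well. The other probe sets of Ttr, Clba1, Polr1e and Kcna4 had the sign of the named one and did not pass. The other 3 probe sets of Kcnd3 were dim, with differences of -0.56, -0.62 and -0.25 that did not pass, and of the other 4 probe sets of Masp1 only 1 passed, at -1.07 (limma adjusted p = 0.0476). Averaging all probe sets of a gene gave smaller differences that still passed for Kcnd3 (-0.72), Masp1 (-1.16), Lrrc52 (1.10) and Esr1 (2.24).

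**Figure D2:**
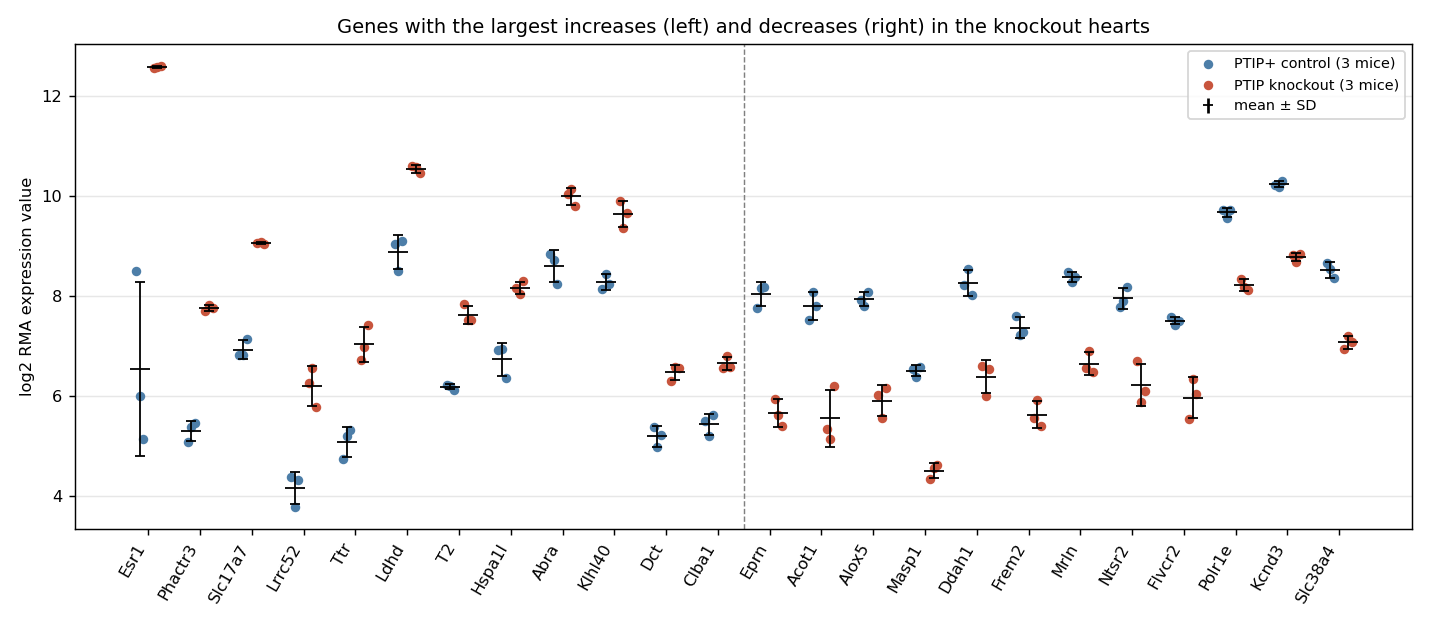
RMA expression values (log2, y axis) in each mouse of the 12 genes with the largest increases and the 12 with the largest decreases (x axis, parted by the dashed line), with PTIP+ controls in blue, PTIP knockouts in red, and bars for mean ± SD of 3 mice. The groups do not overlap for any of the 24 genes, as the naming rule required, and control 1 reads 8.49 on Esr1.

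Across the genome, 86 of 45037 probe sets passed, 30 higher and 56 lower in the knockout mice. Lower values made up 65.1% of them, and 52.2% of the 90 that passed when each array was centred on its median. By representative probe sets, 52 of 18194 genes passed, 20 higher and 32 lower, with 17 increases and 28 decreases of at least 2-fold. The called genes had 48 other probe sets, all 48 of the same sign and 41 with an unadjusted p under 0.05. At an unadjusted p under 0.05 there were 4083 probe sets (9.07%), and the 2 groups did not overlap for 2914 genes (16.0%, where chance gives 10% on average). Another split of the arrays, knockout 1 with controls 2 and 3 against the rest, gave 4421 probe sets at that p. Neither share alone thus shows an effect of the deletion, and overlap was not counted for other splits. The counts for the real groups rest on all 6 arrays. With limma, 0 probe sets passed without knockout 1 (3790 at an unadjusted p under 0.05) or without control 2 (3532). The count was 1 without knockout 2, 7 without knockout 3, 21 without control 1 and 18 without control 3. All 86 kept their sign and an unadjusted limma p under 0.05 whichever mouse was left out, but they were chosen with the same arrays.

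Genes of the cardiac potassium channels differed in both directions in the knockout ventricles, and Kcnd3 fell. By sign, 15 members of the list were lower and 11 higher, with a median difference of -0.06. At an unadjusted limma p under 0.05, 7 were lower and 4 higher. Of 26 measured members of that list, 1 fell and none rose when adjusted over all probe sets, while adjusted over the list alone 5 fell and 1 rose. Besides Kcnd3, Kcna4, a pore-forming subunit of the slow transient outward current, read 6.64 ± 0.15 in the knockout mice and 7.80 ± 0.24 in the controls (SD, n = 3 each), a difference of -1.16 (limma adjusted p = 0.0507 over all probe sets, 0.00127 over the list alone). Kcnip2, the accessory subunit of the Kcnd channels, read 10.62 ± 0.32 against 11.81 ± 0.14 (SD, n = 3 each), a difference of -1.19 (limma adjusted p = 0.0728 over all probe sets, 0.00185 over the list alone). Its other bright probe set, 1425870_a_at, differed by -1.54 (limma adjusted p = 0.0909), and a dim one, 1421783_a_at, by 0.05. Kcne1, a partner of the slow delayed rectifier channel, differed by -1.14 on its representative probe set (limma adjusted p = 0.0881) and fell by 2.77 on the probe set 1420672_at (limma adjusted p = 0.00996). The list as a whole had a mean difference of -0.16 and did not pass with camera (adjusted p = 0.0629), nor with an estimated correlation (adjusted p = 0.777), and passed with fry in one direction (adjusted p = 0.0423) and in either direction (adjusted p = 1.57e-05). With 1 mouse left out, the list passed without control 1 (camera adjusted p = 0.0432) and without knockout 3 (camera adjusted p = 0.0498). It did not pass without any of the other 4 mice, and its camera adjusted p was 0.232 without control 2. In all, the list passed in 7 of 20 other settings.

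**Figure D3:**
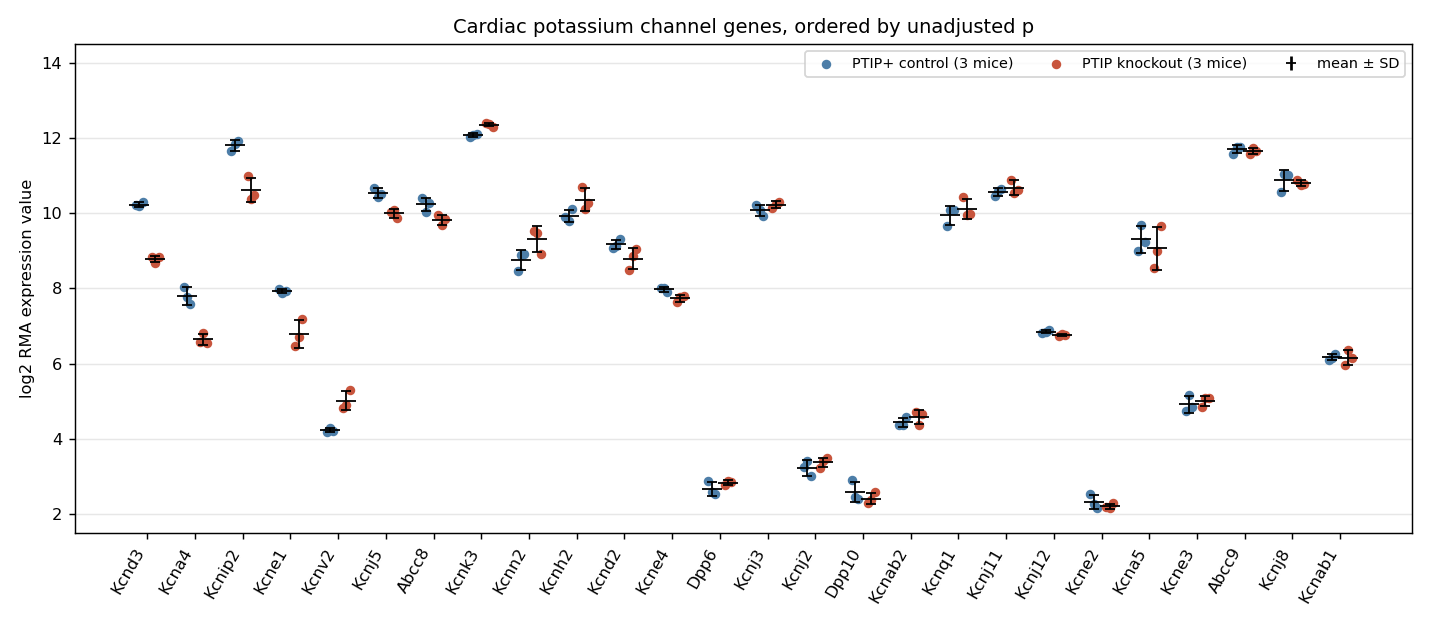
RMA expression values (log2, y axis) of the 26 measured genes of the cardiac potassium channel list in each mouse (x axis, ordered by unadjusted p), with PTIP+ controls in blue, PTIP knockouts in red, and bars for mean ± SD of 3 mice. Kcnd3, Kcna4, Kcnip2 and Kcne1 have no overlap between the groups and lie lower in the knockouts, and Kcnv2 lies higher.

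Few other genes of excitation and contraction passed over their list alone. None of the 17 measured sodium, calcium and pacemaker channel genes passed over all probe sets or over the list alone (mean -0.12, camera adjusted p = 0.569). In the list of gap junctions and the intercalated disc, none of 18 passed over all probe sets and 1 fell adjusted over the list alone, the connexin gene Gja3 with a difference of -0.65 (camera adjusted p of the list = 0.183). Calcium handling genes had a mean difference of 0.04 with none of 22 passing in either way, and Ryr2, the calcium release channel, and Atp2a2, the calcium pump, differed by -0.11 (SE 0.10) and -0.04 (SE 0.10) on their brightest probe sets. The other Ryr2 probe set differed by -0.26, and the 5 other Atp2a2 probe sets, all lower, by -0.85 to -0.02, none passing. The mean of all Atp2a2 probe sets was -0.30. The sarcomere list had a median of -0.00275 and a mean of 0.03 over 30 genes, none of which passed in either way. Myh6, the main adult myosin heavy chain, differed by -0.06 (SE 0.10) and on its other probe set by -0.17. Myh7, its fetal counterpart, differed by 0.82 (SE 0.31, limma adjusted p = 0.494), and by 0.42 without control 3, which read 9.02. Of 24 cardiac transcription factors none passed over all probe sets, and Tbx5 was higher by 0.52 adjusted over the list alone. Among 17 fetal and hypertrophy markers, none passed over all probe sets, and adjusted over the list alone 3 were lower: Nppb by a difference of -1.35, Acta1 by -0.88 and Ankrd1 by -0.68. Nppa, which encodes another natriuretic peptide, differed by 0.54 (limma adjusted p = 0.458), so the 2 peptide genes had opposite signs. The 27 adrenergic and G protein signalling genes on the list, 19 of them measured, had none that passed (camera adjusted p = 0.663). Fry in either direction, which asks for changes of any sign, passed for 5 lists of this paragraph: sodium, calcium and pacemaker channels (adjusted p = 0.000855), gap junctions (adjusted p = 0.000975), cardiac transcription factors and fetal markers (adjusted p = 9.41e-05 each) and adrenergic signalling (adjusted p = 0.0401).

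Genes of H3K4 methyltransferase and demethylase complexes, only some of them those around PTIP, had small differences. None of the 22 measured genes of that list passed over all probe sets or over the list alone. Their mean difference was 0.01 with an SD of 0.10 over genes (camera adjusted p = 0.879), and Pagr1a, which had the smallest p, differed by 0.26 (SE 0.23), or 0.06 without knockout 1.

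Among metabolic genes, Acot1 was the only member of the fatty acid oxidation list that passed over all probe sets. Adjusted over the list alone, Acot1 fell and Esrrb, an estrogen-related receptor, was higher by 0.63, while the 35 measured members had a mean of -0.07 (camera adjusted p = 0.559, fry in either direction adjusted p = 0.00337). The 42 oxidative phosphorylation genes had a mean of -0.03, which turned to 0.01 when each array was centred on its median, and none passed in either way (camera adjusted p = 0.148). That list passed in 3 of 20 other settings: a variance trend (camera adjusted p = 0.0148), the mean of all probe sets of a gene (camera adjusted p = 0.0351) and camera on ranks (adjusted p = 0.0403). The 22 glycolysis and glucose uptake genes had a mean of 0.09 with none passing in either way, and Hk1, a hexokinase, had the smallest p with a difference of 0.46 (SE 0.12, camera adjusted p of the list = 0.181).

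Among the lists of stress, turnover and division, 3 passed with camera and none of these 3 passed with an estimated correlation. Interferon response genes were higher by a mean of 0.24, with 20 of 24 higher, among them Gbp3, a GTPase of host defence, at 0.54 and Ifit2, an antiviral RNA-binding protein, at 0.44 (camera adjusted p = 0.00130, adjusted p = 0.777 with an estimated correlation). Cell cycle genes were lower by a mean of -0.21, with 23 of 27 lower, among them the mitotic kinase Aurkb at -0.74 and Ccnd1, cyclin D1, at -0.46 (camera adjusted p = 0.00130, adjusted p = 0.800 with an estimated correlation). No member of either list passed over all probe sets or over the list alone, and single mice moved both means. The interferon mean was 0.16 without knockout 1 (camera adjusted p = 0.0448), and knockout 2 at 0.10 lay near control 2 at 0.08. The cell cycle mean was -0.14 without control 2 (camera adjusted p = 0.135), where the call ended, and -0.34 without control 3, and control 3 at -0.26 lay below knockouts 1 and 3 at -0.17 and -0.19. The list of muscle atrophy, autophagy and proteasome was higher by a mean of 0.14, with 19 of 22 higher (camera adjusted p = 0.0410, adjusted p = 0.777 with an estimated correlation). None of its members passed over all probe sets, and adjusted over the list alone 3 were higher: the ubiquitin ligase gene Fbxo32 by 0.70, Gabarapl1, of autophagosome formation, by 0.55 and the mitophagy receptor gene Bnip3 by 0.39. Without knockout 2, control 1 or control 3 that list did not pass, with camera adjusted p of 0.111, 0.197 and 0.0571. With all 6 arrays it did not pass with array weights (camera adjusted p = 0.117), renewed quantile normalization (camera adjusted p = 0.0567) or the replicate block (camera adjusted p = 0.0581). Nor did it pass with camera on ranks (adjusted p = 0.0722) or fry in one direction (adjusted p = 0.0802). It passed with fry in either direction (adjusted p = 0.0279). Of 20 other settings, this list passed in 10, the interferon list in 17 and the cell cycle list in 16. Of the 10 ways to split the 6 arrays in 3 and 3, 6 gave at least as many passing lists as the 4 counted here, cell type markers included.

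The other stress lists did not pass with camera. Of 25 p53 targets none passed in either way, with a mean of 0.03 and a median of -0.01, and Cdkn1a, the p53 target that blocks the cell cycle, differed by -0.18 (SE 0.33). The integrated stress and unfolded protein response list had a mean of 0.10 and none of 28 passing in either way, with the glutathione-degrading enzyme gene Chac1 at 1.00 and the transcription factor gene Atf5 at 0.72. Its mean per mouse was 0.18, 0.20 and -0.09 in the knockouts, and leaving out knockout 3 gave 0.19 and knockout 2 0.04. Of 27 heat shock and oxidative stress genes none passed over all probe sets, and adjusted over the list alone Hspb1, a small heat shock protein, and Srxn1, a sulfiredoxin, were higher by 0.50 and 0.64 while Gpx3, a plasma glutathione peroxidase, differed by -0.50 (fry in either direction, adjusted p = 0.00142). Inflammatory cytokine and acute phase genes had a mean of 0.04, a median of -0.01 and camera direction down. Their mean per knockout mouse was 0.16, -0.09 and 0.06. Adjusted over the list alone 1 of 30 passed, the prostaglandin synthase gene Ptgs2 at -0.62 (fry in either direction, adjusted p = 0.0390). The circadian clock list had a mean of 0.20 with none of 18 passing in either way, and the immediate early genes a mean of -0.17 with none of 24 (camera adjusted p = 0.0629 for both lists). The immediate early mean was -0.02 without control 1 and -0.37 without control 3, where the list passed (camera adjusted p = 4.87e-05), and control 3 at -0.41 lay below every knockout mouse. That list passed in 8 of 20 other settings. The clock mean was 0.11 without control 2 (camera adjusted p = 0.570), and the list passed in 3 of 20 other settings, among them without control 3 (mean 0.26, camera adjusted p = 0.00693). The extracellular matrix list had a mean of 0.01, a median of -0.02 and camera direction down, with none of 34 passing in either way, and the 24 measured cytosolic ribosomal protein genes had a mean of 0.03 with none passing.

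Markers of other cell types were examined for changes in the makeup of the tissue, and no marker of any list passed over all probe sets. Macrophage markers passed as lower, with all 17 lower and a mean of -0.29, among them the mannose receptor gene Mrc1 at -0.51, the haemoglobin scavenger receptor gene Cd163 at -0.38 and Adgre1 at -0.47 (camera adjusted p = 2.04e-06, adjusted p = 0.910 with an estimated correlation). None of these markers passed over the list alone, and the mean was -0.16 without knockout 2 and -0.42 without knockout 1. Knockout 1 at -0.04 lay between controls 1 and 3 at -0.05 and -0.04, so the difference came from the other 2 knockout mice. The list passed in 17 of 20 other settings, all of them with camera's preset correlation of 0.01, while its estimated correlation was 0.42. It did not pass with fry in one direction (adjusted p = 0.999886) or in either direction (adjusted p = 0.252). None of the other 11 cell type lists passed in the main setting. Mesothelial and epicardial markers had a mean of -0.43 (camera adjusted p = 0.193), and their mean was 0.50 higher than the controls' in 1 knockout mouse and lower in the other 2. That list passed without knockout 3 (mean -0.89, camera adjusted p = 0.000117), without control 3 (mean -0.70, camera adjusted p = 0.0256) and with centring (camera adjusted p = 0.0487), and its mean was 0.05 without knockout 2. Knockout 2 had the lowest mean of the 6 mice for the macrophage list (-0.56), the mesothelial list (-1.38) and the cell cycle list (-0.28), and control 3 was low for the last 2 (-0.55 and -0.26). Whether the lower cell cycle genes follow from the makeup of the tissue was not tested. Adjusted over the list alone, 1 skeletal muscle marker was lower, Tnni2, a fast troponin I, at -1.04, 1 adipocyte marker was lower, Cidea at -0.76, 1 atrial marker was higher, Stard10 at 0.65, and 1 lymphocyte marker was higher, the immunoglobulin heavy chain gene Ighm at 1.00. The means of these lists were -0.10 for skeletal muscle, -0.00153 for adipocytes, 0.08 for atrial myocytes and 0.11 for lymphocytes. These means depended on single mice: that of lymphocytes was -0.09 without knockout 1, that of atrial myocytes 0.28 without control 1 (camera adjusted p = 0.0404) and -0.09 without control 3, and that of skeletal muscle 0.07 without control 1 and -0.23 without control 2 (camera adjusted p = 0.0495). The remaining lists had no marker that passed in either way, with means of 0.14 for Schwann cells and neurons, 0.11 for smooth muscle and pericytes, -0.06 for neutrophils, -0.04 for fibroblasts, -0.04 for erythroid cells and 0.01 for endothelium. The smooth muscle mean was 0.04 without knockout 1 or control 1, and the Schwann cell mean was 0.07 without knockout 2. Leaving out 1 mouse turned the sign of the mean of neutrophils, fibroblasts, erythroid cells, endothelium and adipocytes in at least 1 case each. Centring each array on its median turned the sign of the means of fibroblasts, erythroid cells, adipocytes and adrenergic signalling.

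**Figure D4:**
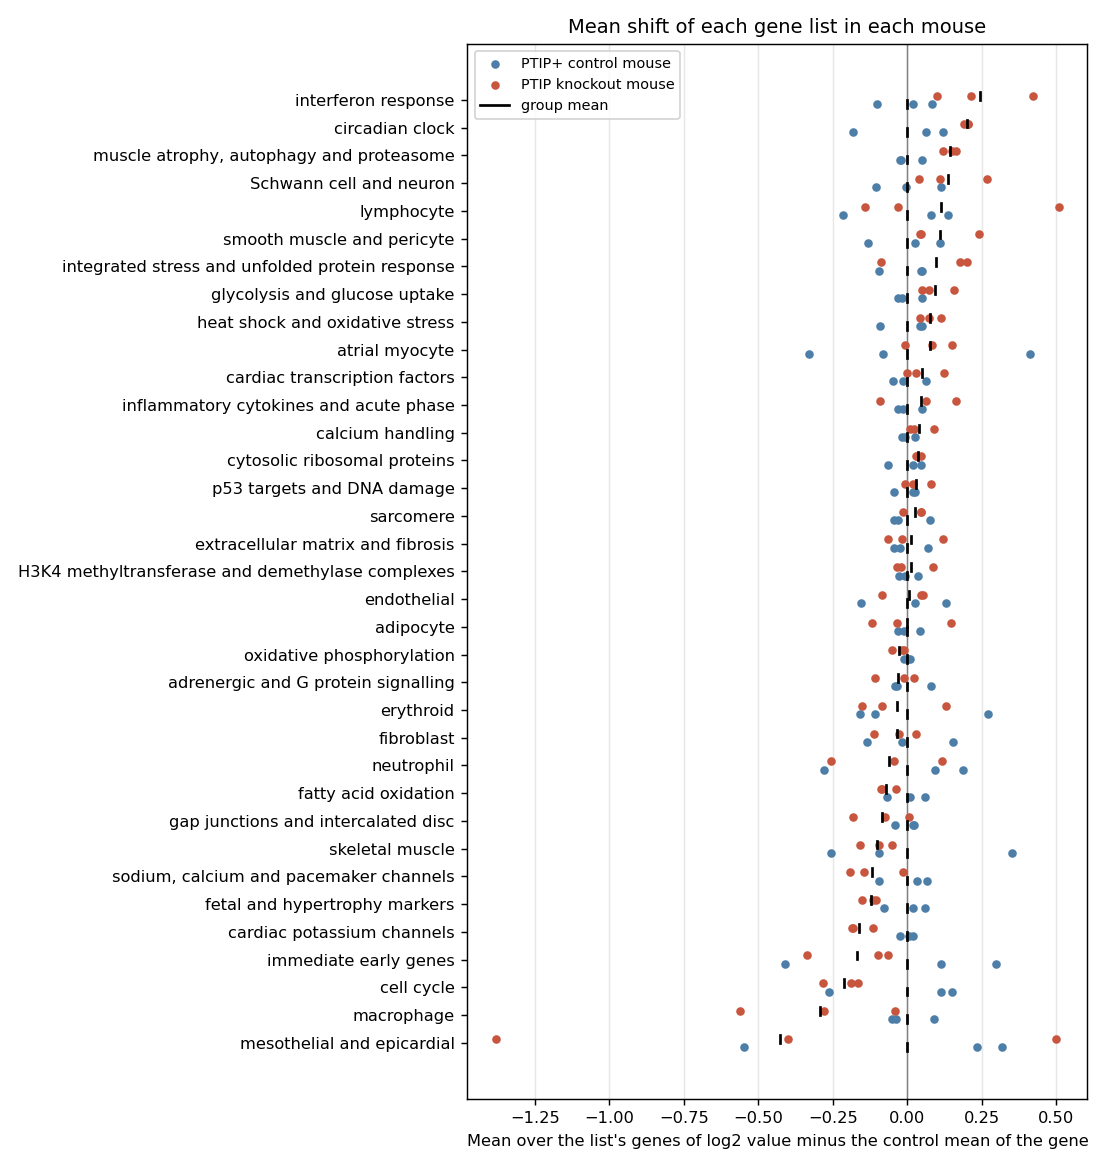
Mean over each list's genes of the log2 value minus the control mean of the gene (x axis, log2 units) for the 35 gene lists (y axis), with 1 blue point for each PTIP+ control, 1 red point for each PTIP knockout and a black bar for each group's mean of 3 mice. The lists run from interferon response at 0.24 down to the mesothelial and epicardial markers at -0.43, whose knockout points spread widely.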

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

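Counting a gene when any of its probe sets passed (63 genes) was chosen after seeing the data, and the other alternatives were planned. With limma, passing probe sets and genes numbered 185 and 111 with a variance trend, 51 and 30 with a robust prior, and 42 and 24 with the filter at the 25th percentile. Array weights gave 204 probe sets and about 1.1e+02 genes, 50 higher and 56 lower. At an adjusted p under 0.01 there were 4 and 3, and under 0.1 there were 196 and 108. The mean of all probe sets of a gene gave 124 genes, and the test without moderation 1 probe set (3639 at an unadjusted p under 0.05). The other filter, renewed quantile normalization, centring and a fold of 1.5 kept both counts within a factor of 1.5. Leaving out 1 mouse gave 0 to 21 probe sets, 0 to 13 genes, and 0 passing Paxip1 probe sets in every case, and leaves fewer mice. Knockout 3 and all controls alone, which share the leading digits of their description number, gave 0 probe sets, 0 genes and 0 Paxip1 probe sets (2348 probe sets at an unadjusted p under 0.05), and the lone knockout is there assumed to vary like the controls. The replicate block gave 0 probe sets, 0 genes and 0 Paxip1 probe sets (3392 at an unadjusted p under 0.05, smallest adjusted p 0.0890). No label ties the numbers to pairs, and deviations of same-numbered mice correlated at -0.15, -0.08 and -0.01 over probe sets. Differently numbered mice were not compared in this way, so a tie between same-numbered mice stays open.

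The 4 passing lists became 9 with a variance trend, 7 with centring, 7 with the mean of all probe sets, 10 with fry in either direction, 1 with fry in one direction and 0 with an estimated correlation, and 3 to 6 when a mouse was left out. Of the 31 lists that did not pass, 15 passed in no other setting, 11 in 1 and 5 in 3 or more. The causes of these differences were not tested, the effect of fewer mice included. The log2 differences of single genes changed sign 24 times and the means of lists 45 times over all settings, and none of these values passed in either setting. Kcnip2 passed in 4 of 16 settings, with differences from -1.37 to -0.89 and adjusted p from 0.0137 to 0.753. Dim probe sets limit what can be seen, since the median of all probe set means was 5.19.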

Other observations

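The tests of cardiomyocyte share, RNA integrity, p53 response, transgene RNA, mixed RNA, neighbouring DNA, single probe sets, splits for probe sets and genes, and signal level were chosen after the result was seen, and the splits for lists were planned. Genes of this paragraph and the next were also chosen after their values were seen. Slc40a1, the iron exporter ferroportin, fell by 1.01 on the log2 scale (limma adjusted p = 0.0476). Tfrc, the transferrin receptor that takes up iron, differed by -1.09 (SE 0.22, limma adjusted p = 0.170) from 11.95 ± 0.33 in the controls to 10.85 ± 0.32 (SD, n = 3 each) on its brightest probe set, and by -1.42 and -2.07 on the other 2. The 3 transferrin receptor control probe sets of the array, which were outside the tested set, differed by -1.31, -1.10 and -1.29, with all 3 knockout mice below all 3 controls (exact permutation p = 0.1 each, the smallest possible).

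Slc38a2, an amino acid transporter like Slc38a4, fell by 0.94. Ppp1r3c, which targets a phosphatase to glycogen, fell by 1.07, Angpt1, a ligand of the endothelial receptor Tek, fell by 1.20, and Tnnt1, the slow troponin T of skeletal muscle, fell by 1.01. Stc2, a secreted glycoprotein, fell by 0.91. Among the increases, the transcript 2900052N01Rik, left out of the named genes as a predicted gene, rose by 3.91, more than any gene but Esr1. Ptprn, a protein of secretory granules, rose by 1.13. In the circadian clock list, Ciart differed by 1.39 (limma adjusted p = 0.342), with 7.97 ± 0.89 in the controls and 9.36 ± 0.23 in the knockout mice (SD, n = 3 each). Clock differed by -0.52, and the hours of tissue collection are not analysed here.

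Kcnip2, Kcnd3, Kcna4 and Kcne1 had a mean log2 difference of -1.23, with an SD of 0.14 over the 4 genes. A smaller share of cardiomyocyte RNA could lower the sarcomere genes too. Their median was -0.00275 (95% bootstrap interval over genes, not over mice, -0.0288 to 0.0359). Their mean per mouse lay between -0.05 and 0.08. The sarcomere genes thus did not fall to the bound of -0.617, but whether they could have shown such a fall was not tested. Myh6 averaged 13.5 over all arrays, near the top of the scale, where a fall may be compressed. Normalisation between arrays may also hide part of a fall in cells that supply much of the RNA. The bound was set from the 4 genes, which had the smallest p of their list. A loss of cardiomyocyte RNA, large or small, thus stays open. The mean of the 4 genes without control 1 was -1.22 (SE 0.09 over the 4 genes, not over mice). They had been chosen by p with that array included, so a large move was unlikely, and this decides little about its RNA integrity. Without control 1, Kcnd3 passed (limma adjusted p = 0.0332). Kcnip2, Kcna4 and Kcne1 did not, with limma adjusted p of 0.107, 0.0855 and 0.160. The knockout mice had larger actin differences (1.51, 1.45 and 1.64) than controls 2 and 3 (1.17 and 1.38). Lower RNA integrity of the knockout samples thus stays open. The p53 targets did not rise as a whole, with a median of -0.0119 (95% bootstrap interval over genes -0.0798 to 0.140). At an unadjusted limma p under 0.05, 3 of 25 targets were higher and 0 lower. A p53 response to Cre in a few targets thus stays open. The Cre transgene itself cannot be told apart from the loss of Paxip1, because 0 arrays are labelled with the transgene and without the deletion. The null allele of the knockout mice, which does not depend on tamoxifen, cannot be told apart from the induced deletion either. A hypothesis that stays open is that loss of PTIP lowers several subunits of the repolarising potassium channels. Mice with the transgene, tamoxifen and no floxed or null allele would test the transgene. The 4 genes would be lower there too if the transgene were the cause, and unchanged if the loss of PTIP were. Mice with a floxed and a null allele, tamoxifen and no transgene would test the null allele.

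The Esr1 probe set 1421244_at rose by 6.02 while the other Esr1 probe sets rose by 0.37 at most, which is consistent with RNA of the fusion transgene hybridising to 1 part of Esr1. The level of 8.49 in control 1 may come from knockout RNA in that sample, and 5.16% of such RNA would be needed. The 16 other probe sets at least 4-fold higher in the knockout mice than in controls 2 and 3 were higher in control 1 by 1.09 (SE 0.41), where that share predicts 0.34. This first looked like support, but choosing probe sets by their low values in the other 2 controls can lift the third, so the same comparison was added for the other controls. It gave 1.00 (SE 0.24) for control 3, which had the lowest Esr1 value, and -0.24 (SE 0.19) for control 2. A shift of this size thus also arose in a control without raised Esr1, so the comparison does not decide whether RNA was mixed. If this probe set reads the transgene, a transgene in control 1 expressed as in the knockout mice is argued against, since control 1 differed from their mean by -4.07 (SD of the knockout mice 0.02) and controls 2 and 3 read lower still. A weakly expressed transgene or the mouse's own Esr1 were not tested.

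The called genes may in part reflect DNA of another strain carried along with the targeted Paxip1 alleles, or single faulty probe sets. Within 20 Mb of Paxip1 lay 2 of the 52 called genes, Gm9899 and Sorcs2, where 0.767 were expected (two-sided Fisher's exact p = 0.179), so such DNA near Paxip1 does not account for most of them. Of the 25 other probe sets of called genes above the median level, 100% had the same sign, against 72.3% for genes not called. These belong to 16 of the 52 called genes, and for the other 36, which have no such probe set, a faulty probe set stays open. Strain differences elsewhere in the mixed background stay open as untested.

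With 10 splits of the 6 arrays, a share under 0.05 cannot be reached. The real split gave 86 probe sets and the highest other split 0, in 1 of 10 splits as many, and 52 genes against 0, again in 1 of 10. Every other split has knockouts and controls on both sides. A true group difference would widen the spread there and hold the counts down, so the 0 is no measure of arrays without a difference. For gene lists, 6 of 10 splits gave at least 4, and the highest other split gave 9. The split of knockout 1 with controls 2 and 3 against the rest gave 4421 probe sets at an unadjusted p under 0.05, more than the 4083 of the real one, which points to a structure of the arrays beside the groups. Called increases were dimmer than called decreases by a difference of -0.76 in mean level (7.34 against 8.10, permutation p = 0.118), which did not pass.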
